A study of Homo sapiens with 12 samples.

How the data were processed

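Gene expression was measured by RNA sequencing in HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen and is widely used for transfection. Per the labels' protocols, plasmids were delivered with a lipid reagent and total RNA was extracted with TRIzol. The protocols name a modified eCLIP library construction, a small RNA kit and a stranded total RNA kit for low input, while the design text of the series names Trace-seq. Which of these made the libraries used here is not given in the sources used here. The 12 libraries fall into 6 groups of 2: for each of the stop codons TAA, TAG and TGA, a RESTART v3 group and a group that the labels call gctrl, an abbreviation they do not expand.

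The deposited values are FPKM (fragments per gene, normalized to transcript length and to the number of mapped fragments), in 1 table per stop codon. The submitters' processing notes name Trim Galore for trimming, STAR 2.7.10b for alignment, SAMtools 1.14 and HTSeq, with the genome build GRCh38. The tool that turned counts into FPKM, the annotation, the strand setting and the filter that set which genes each table lists are not given in the sources used here. Without a stated strand setting, a gene and its antisense partner cannot be told apart, and genes with near-identical copies are uncertain for the same kind of reason.

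Columns were assigned to samples from their names, which hold the stop codon, a number that is 1 or 3, and a number that is 1 or 2. The value 3 was read as RESTART v3, the value 1 as gctrl by exclusion, and the last number as the replicate. This reading is an inference. If the arms were exchanged, every direction given here would reverse and the counts of changed genes would stay as they are. All 12 value columns were used.

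The tables list 13503, 13438 and 13385 genes for TAA, TAG and TGA, with 12760 genes in all 3 and 14151 in any. No value is 0. The deposited FPKM carry no counts, so the depth was estimated from the steps between low values. Between 72.3% and 82.2% of the genes with a mean under 0.1 FPKM lay on ratios of whole read numbers up to 6 within 0.01 log2, against 7.20% to 11.7% by chance. From these steps the libraries hold approximately 10000000 to 14200000 fragments each. Because the steps explain only part of the low values, these depths are approximate, and no count test was run.

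Within each table, genes with at least 1 FPKM in at least 2 of the 4 libraries were tested, which left 11705, 11683 and 11692 genes. Values were used as deposited, as log2(FPKM + 1), and RESTART v3 was compared with gctrl by limma 3.58.1 in R 4.3.3 (a moderated test with a mean-variance trend, 2-sided). Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes at low levels. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. The change across codons was fitted with limma on all 12 libraries with stop codon and arm as terms (8 residual degrees of freedom) over the 11515 genes tested in all 3 tables. Whether a gene's change differed between codons was tested with the interaction of arm and codon (an F test with 2 degrees of freedom) and with the 3 pairwise differences. Because the tables may have been normalized separately, levels were compared only within a table, and comparisons between codons use fold changes.

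Gene lists were fixed before the data were examined, as were the tests, the alternatives (apart from those named below) and the rule for the genes named. The 38 lists covered the H/ACA particle, the stand-alone pseudouridine synthases, the C/D particle, termination and stop codon decoding, nonsense-mediated decay factors and targets, several stress responses, tRNA and ribosome genes, the cell cycle, metabolism, small RNAs, histone genes and markers of other cells. Lists with at least 4 tested members were tested with limma's camera, with a preset correlation between genes of 0.01 and again with an estimated correlation. Camera asks whether a list's genes stand apart from the other genes. Limma's fry was also planned. It asks whether a list's genes changed at all, whatever the other genes did, and its p-values are given without adjustment over the lists. Within a list, the count of changed genes was also taken with p-values adjusted over the list alone.

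Genes are named by this rule. In each comparison they are the passing genes with the largest changes, up to 10 in each direction, with RESTART v3 libraries outside the range of the gctrl libraries (across codons, with the same direction in all 3). Where fewer than 5 passed in a direction, the genes with the smallest p-values fill the list to 5 and are stated not to have passed. DKC1, NOP10, NHP2, GAR1, UPF1, SMG1, ETF1 and GSPT1 are given throughout, and up to 4 members with the smallest p-values are given for a list. Clone-named and pseudogene-named features were not named, and results for some genes are not reported here.

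Before the main tests were run, the code was tested on simulated libraries with known changes. Their means and spread were fitted to the deposited values. The changed genes were drawn only from those above a level higher than the filter, so recovery of the lowest tested genes is not covered. With 50 genes changed at each size, 34% of 1.25-fold, 96% of 1.5-fold and 100% of 2-fold changes were recovered in the TAA design. The TAG design recovered 30%, 84% and 98%, and the TGA design 16%, 76% and 100%. The design across codons recovered 92%, 100% and 100%, and the test of a difference between codons 6%, 70% and 96%. Of the called genes, 9 of 174, 8 of 164, 6 of 152 and 9 of 205 were false in the TAA, TAG, TGA and across-codon designs, and no gene was called when no change was simulated. Each design recovered all 5 moved lists with the preset correlation. With an estimated correlation, 0 of 5 were recovered within a codon and 5 of 5 across codons. For lists moved by the simulated amount, it thus had no power with 4 libraries. The simulated genes varied independently of each other, so the simulation cannot show whether the preset correlation is too low for the real lists. For the ribosomal protein genes in TAA, the estimated correlation was 0.54.

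Alternatives covered the pseudocount (0.1 FPKM), the filter (none, or at least 5 FPKM), median-ratio scaling, quantile normalization, limma without the trend, a fit of all 6 groups together, the replicate number as a block, and each library or stop codon left out. Chosen after seeing the data were a correction for transcript length and GC content, quantile normalization of the list tests, and another reading of the column names. Transcript lengths and GC content came from the basic set of GENCODE transcripts, matched to gene symbols with the help of the RefSeq gene table. Lengths were found for 13467 of the 14151 genes (95.2%). The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.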

Results

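RESTART is a method for reading through premature stop codons. A guide RNA of the box H/ACA class directs the cell's own pseudouridine synthase, dyskerin, to the uridine of a premature stop codon, and the pseudouridine allows the ribosome to insert an amino acid there. The version named RESTART v3 adds a near-cognate tRNA that can decode the modified codon. The series was designed to look for off-target effects of RESTART v3 on RNA levels throughout the transcriptome, with gctrl as the reference for each of the 3 stop codons.

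Expression was profiled in 12 libraries from HEK293T cells, 2 for each arm of TAA, TAG and TGA. FPKM totals per library ranged from 454971 to 507316, and the depth estimated from low values from 10000000 to 14200000 fragments. Cytosolic ribosomal protein genes held 24.3% to 27.8% of the FPKM, and the 10 highest genes 9.15% to 10.4%. Directions rest on reading the number 3 in the column names as RESTART v3, which the names imply and do not spell out.

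The arms were close to each other at every codon. Across genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) between a gctrl and a RESTART v3 library was 0.993 to 0.996. Of the genes tested, 99.7% in TAA, 99.7% in TAG and 99.5% in TGA lay within 1.5-fold. The SD of the log2 ratio between arms was 0.13 in TAA, 0.13 in TAG and 0.16 in TGA. When the same 4 libraries were instead split by replicate number, it was 0.11, 0.12 and 0.13, so that the arms differed by 1.16, 1.12 and 1.31 times that spread. At least a 2-fold change at any p was seen for 9 genes in TAA, 2 in TAG and 12 in TGA, against 10, 1 and 8 in the split by replicate number.

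**Figure D1:**
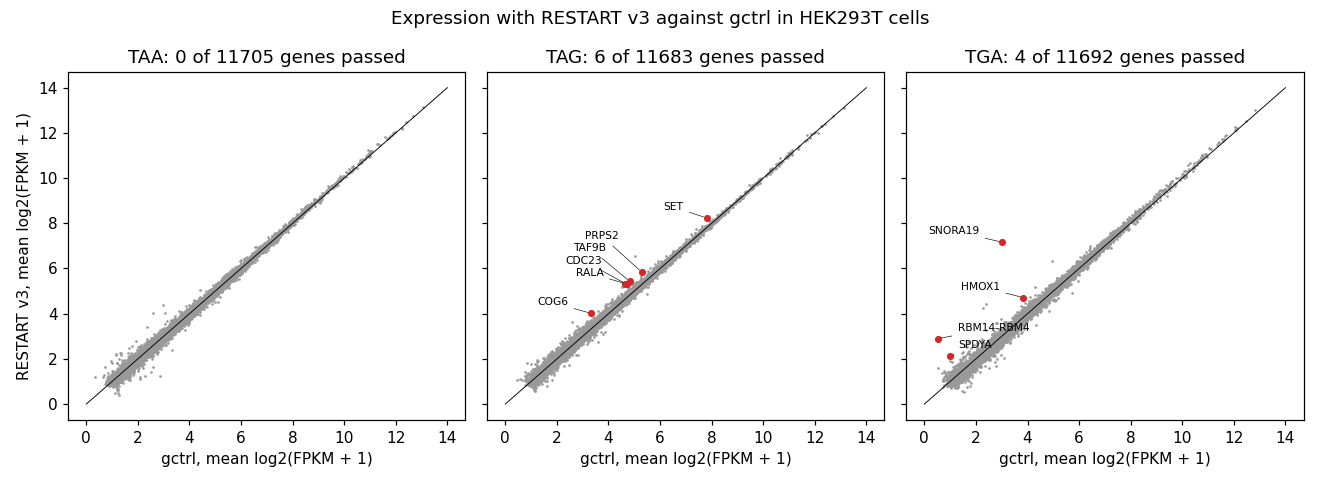
Mean log2(FPKM + 1) of the 2 RESTART v3 libraries (vertical axis) against that of the 2 gctrl libraries (horizontal axis), 1 point per tested gene, for TAA, TAG and TGA, with the line of equal expression. Red points passed limma's test at an adjusted p under 0.05: 0 genes in TAA, 6 in TAG and 4 in TGA, all above the line.

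At TAA, no gene passed the test between RESTART v3 and gctrl, while ribosomal protein and glycolysis genes stood above the rest by small amounts. Cytosolic ribosomal protein genes rose as a set, with a median log2 fold change of 0.12 and 71 of 78 members positive. This call, and those of the 2 lists below, were lost with an estimated correlation between genes (adjusted p = 0.893 for each). That test recovered 0 of 5 moved lists within a codon in simulation, so the loss cannot decide these calls. RPL35 (0.30), RPS28 (0.24) and RPL37 (0.22) had the smallest p-values among the ribosomal protein genes. Genes of hypoxia and glycolysis rose as a set by a median of 0.13, with 20 of 22 positive, among them the glycolytic enzymes ALDOC (0.50), ALDOA (0.32), PGK1 (0.26) and ENO1 (0.25). Oxidative stress genes rose as a set by a median of 0.06, with HMOX1, which degrades heme, at 0.45 and the metallothionein MT1X at 0.31.

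The adjusted p from camera was 2.84e-14 for the ribosomal protein genes, 8.72e-07 for hypoxia and glycolysis and 0.0164 for oxidative stress, and these were 3 of 30 lists tested. The medians kept their sign under median-ratio scaling and quantile normalization, but under the latter the ribosomal protein median was 0.02 (adjusted p = 0.0673) and oxidative stress was not called either (adjusted p = 0.162). Oxidative stress was also not called after the length and GC correction (median 0.04, adjusted p = 0.118) or without gctrl-TAA replicate 2 (adjusted p = 0.0656) or RESTART v3-TAA replicate 2 (adjusted p = 0.117). The ribosomal protein median was 0.06 without gctrl-TAA replicate 2 (adjusted p = 2.98e-08), and without RESTART v3-TAA replicate 1 those of hypoxia and glycolysis and of oxidative stress were 0.20 and 0.09 (adjusted p = 6.64e-07 and 0.0309). The FPKM totals in TAA were 497265 and 482345 in gctrl and 507316 and 506622 in RESTART v3. Over all genes tested, 0 members of these lists passed. Adjusted over the list alone, 0 ribosomal protein genes, 5 hypoxia and glycolysis genes and 1 oxidative stress gene were higher and 0 were lower. For these lists, fry gave unadjusted p-values of 0.121 (ribosomal proteins), 0.104 (hypoxia and glycolysis) and 0.0461 (oxidative stress). When the same libraries were split by replicate number, camera with the preset correlation called 4 lists, 3 higher and 1 lower. Their lowest adjusted p from camera was 0.00622.

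Among single genes in TAA, limma called 0 of 11705, with a lowest adjusted p of 0.0755, while 1268 had an unadjusted p under 0.05 against 585 expected by chance. The nearest on the higher side was the histone gene H2BC12, at 91.3 ± 1.04 FPKM in gctrl and 124 ± 2.82 in RESTART v3 (SD, n = 2; log2 fold change 0.44, SE 0.05, adjusted p = 0.0755). The antisense transcript ZMYM4-AS1 was at 6.25 ± 1.29 and 1.41 ± 0.625 FPKM (log2 fold change −1.60, SE 0.19, adjusted p = 0.0755). Other genes with the smallest p-values, none of which passed, were ZNF436-AS1 (0.84), NDST1-AS1 (0.89), SAXO2 (0.84) and APOC1 (0.34) on the higher side. On the lower side they were the proteasome ATPase PSMC1 (−0.44), the H/ACA RNA SNORA84 (−0.96), the phosphatase PTPN11 (−0.37) and the condensin subunit NCAPG (−0.32). Requiring at least 5 FPKM gave 3 genes. Leaving out a library gave 2 (without gctrl replicate 1), 3 (without gctrl replicate 2), 38 (without RESTART v3 replicate 1) or 19 genes (without RESTART v3 replicate 2).

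At TAG, 6 genes rose and none fell. They were CDC23, a subunit of the anaphase-promoting complex, COG6, a subunit of the Golgi tethering complex, the small GTPase RALA, the transcription factor subunit TAF9B, the nucleotide synthesis enzyme PRPS2 and the histone chaperone SET. CDC23 rose from 24.0 ± 0.383 to 39.4 ± 1.91 FPKM (SD, n = 2; log2 fold change 0.69, SE 0.06, adjusted p = 0.0351). COG6 rose from 9.05 ± 0.551 to 15.2 ± 0.454 FPKM (0.68, SE 0.08, adjusted p = 0.0409), and SET from 222 ± 1.88 to 301 ± 4.92 FPKM (0.43, SE 0.05, adjusted p = 0.0409). The log2 fold changes of the others were 0.61 for RALA, 0.61 for TAF9B and 0.56 for PRPS2. SET has pseudogene copies that could share its reads.

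The test was limma's over 11683 genes, of which 1138 had an unadjusted p under 0.05 against 584 expected by chance. No gene reached 2-fold and passed. The genes with the smallest p-values on the lower side, none of which passed, were HOXB-AS3 (−0.46), the Cajal body RNA SCARNA13 (−0.69), MAP1LC3B2 (−0.75, a near copy of MAP1LC3B), the respiratory chain subunit NDUFS3 (−0.26) and CERS6-AS1 (−0.51). All 6 calls were lost without a filter on low values, under quantile normalization, without the trend, in the fit of all 6 groups and after correction for transcript length and GC content. Under median-ratio scaling 2 remained, and 11 genes were called with at least 5 FPKM. The log2 fold changes themselves moved little under the alternatives (the other column reading aside): CDC23 0.62 to 0.74, COG6 0.61 to 0.74, RALA 0.55 to 0.67, TAF9B 0.53 to 0.63, PRPS2 0.51 to 0.60 and SET 0.37 to 0.45. Leaving out RESTART v3 replicate 1 or 2 gave 0 genes, and leaving out gctrl replicate 1 or 2 gave 10 and 9.

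No gene list stood apart in TAG with camera, out of 30 tested, with a lowest adjusted p of 0.148 and 4 lists at an unadjusted p under 0.05. That lowest value belonged to the H/ACA snoRNAs, the class of RNA that guides pseudouridylation, with a median log2 fold change of −0.31 and 11 of 14 negative. Adjusted over the list alone, 1 of them was higher (SNORA92, 0.48) and 2 were lower, and 0 passed over all genes tested. Ribosomal protein genes had a median of 0.02 (adjusted p = 0.703) and hypoxia and glycolysis genes 0.04 (adjusted p = 0.584). With the replicate number as a block, camera called 1 list in TAG, on the lower side (adjusted p = 0.039). When the same libraries were split by replicate number instead of by arm, it called 2 lists, on the lower side.

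At TGA, 4 genes rose and none fell. HMOX1, the heme-degrading enzyme induced by oxidative stress, rose from 13.3 ± 0.233 to 25.2 ± 0.766 FPKM (SD, n = 2; log2 fold change 0.88, SE 0.07, adjusted p = 0.0204). It lies on chromosome 22 at 35381096 to 35394207 (GRCh38). SNORA19, a box H/ACA snoRNA, had the largest change of those that passed, from 8.48 ± 6.95 to 143 ± 19.6 FPKM (4.15, SE 0.43, adjusted p = 0.0403). SPDYA, an activator of cyclin-dependent kinases, rose from 1.02 ± 0.0126 to 3.34 ± 0.137 FPKM (1.10, SE 0.11, adjusted p = 0.0403).

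SNORA19 lies on the minus strand of chromosome 10 at 119060011 to 119060138 (GRCh38), 128 nt within an intron of EIF3A (119033670 to 119080823), a subunit gene of a translation initiation factor. Its single libraries were at 13.4 and 3.56 FPKM in gctrl and at 157 and 129 FPKM in RESTART v3, which correspond to approximately 22.9, 5.16, 245 and 166 fragments. It was not analysed here for TAA and TAG. RBM14-RBM4, a readthrough transcript that shares its reads with RBM14 and RBM4 and is therefore uncertain, rose from 0.50 ± 0.587 to 6.52 ± 1.60 FPKM (2.37, SE 0.26, adjusted p = 0.0455).

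In TGA, limma gave an unadjusted p under 0.05 for 1581 of 11692 genes against 585 expected by chance, and 3 of the 4 called genes changed at least 2-fold. Genes that did not pass but had the smallest p-values were the readthrough transcript TGIF2-RAB5IF (0.99), the H/ACA RNA SNORA13 (−0.79), the Cajal body RNA SCARNA16 (−1.11), the paraspeckle RNA NEAT1 (−0.72), the smooth muscle actin gene ACTA2 (−0.61) and C8orf58 (−0.99). The count fell to 1 with a pseudocount of 0.1 FPKM, under median-ratio scaling and without the trend, and to 0 without a filter and under quantile normalization. After the length and GC correction it was 6 (3 higher, 3 lower), with 3 of the 4 genes among them and SNORA19 not called. The log2 fold change of SNORA19 was still at least 3.32 under every alternative that could test it (the other column reading aside). The fit of all 6 groups called 124 genes (100 higher, 24 lower). Leaving out gctrl replicate 1 or 2 gave 32 and 77 genes, and leaving out RESTART v3 replicate 1 or 2 gave 18 and 17, with all 4 genes among them each time.

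The ubiquitin-proteasome, heat shock, unfolded protein response and oxidative stress lists rose as sets in TGA. All 4 calls were lost with an estimated correlation between genes (adjusted p = 0.493 for each). That test recovered 0 of 5 moved lists within a codon in simulation, so the loss cannot decide these calls. The ubiquitin-proteasome list had a median log2 fold change of 0.14 with 32 of 34 members positive, including the proteasome subunits PSMC4 (0.32), PSMD7 (0.28) and PSMA5 (0.26). The heat shock list had a median of 0.20 with 13 of 19 positive, including the chaperones HSPH1 (0.29), DNAJB1 (0.43) and HSPE1 (0.29). The unfolded protein response list had a median of 0.07 with 18 of 23 positive, including MANF (0.37) and SEC61B (0.36). Oxidative stress genes had a median of 0.10 with 15 of 18 positive, including the metallothionein MT2A (0.40) and thioredoxin TXN (0.25), and with PGD at −0.25. Adjusted over the list alone, 8 proteasome, 9 heat shock, 2 unfolded protein response and 3 oxidative stress genes were higher, and 1 oxidative stress gene was lower. HMOX1 was the 1 member that passed over all genes tested.

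Ribosomal protein, ribosome biogenesis, decay target and snoRNA host genes also rose as sets in TGA. These 4 calls, and that of hypoxia and glycolysis below, were lost with an estimated correlation (adjusted p = 0.602 for ribosome biogenesis and 0.493 for each of the others). As above, the loss cannot decide these calls. Ribosomal protein genes had a median of 0.14 with 72 of 78 positive, including RPLP2 (0.32) and RPS21 (0.37). Ribosome biogenesis genes had a median of 0.07 with 26 of 33 positive, including NOP16 (0.32). Known targets of nonsense-mediated decay, the pathway that removes mRNAs with premature stop codons, had a median of 0.10 with 27 of 35 positive. Their smallest p-values belonged to the stress genes ATF3 (0.44), DDIT3 (0.43) and GADD45A (0.36) and to SNHG8 (0.26). The snoRNA host genes had a median of 0.09 with 24 of 31 positive, including SNHG17 (0.32), SNHG10 (0.41) and SNHG21 (0.59). Hypoxia and glycolysis genes fell as a set, with a median of −0.16 and 20 of 22 negative, including the metabolic regulators PFKFB4 (−0.44) and PDK1 (−0.30) and the mitophagy receptor BNIP3L (−0.21). Adjusted over the list alone, 0 ribosomal protein, 0 ribosome biogenesis, 1 decay target and 3 host genes were higher, and 2 hypoxia and glycolysis genes were lower, with 0 over all genes tested.

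These were 9 of 31 lists tested in TGA. Their adjusted p-values from camera were 4.67e-10 (ribosomal proteins), 1.78e-08 (proteasome), 1.02e-06 (hypoxia and glycolysis), 0.000898 (heat shock), 0.00119 (decay targets), 0.0013 (snoRNA hosts), 0.00924 (unfolded protein response), 0.00934 (oxidative stress) and 0.00934 (ribosome biogenesis). Their unadjusted p-values from fry ran from 0.00613 (ribosomal proteins) to 0.184 (snoRNA hosts). When the same libraries were split by replicate number, camera with the preset correlation called 3 lists, 2 higher and 1 lower. Under quantile normalization, of the 9, the ubiquitin-proteasome system (median 0.06, adjusted p = 0.0149) and hypoxia and glycolysis (−0.17, adjusted p = 6.42e-09) were still called. The other medians under it were 0.02 for ribosomal proteins, 0.11 for heat shock, 0.03 for decay targets, 0.01 for snoRNA hosts, 0.02 for the unfolded protein response, 0.03 for oxidative stress and 0.03 for ribosome biogenesis. The length and GC correction left ribosomal proteins (median 0.04, adjusted p = 0.083), oxidative stress (0.08, adjusted p = 0.0505) and snoRNA hosts (0.06, adjusted p = 0.157) not called. Without gctrl-TGA replicate 1, oxidative stress (adjusted p = 0.0733) and snoRNA hosts (0.05, adjusted p = 0.092) were not called, and without RESTART v3-TGA replicate 1, ribosome biogenesis was not (0.02, adjusted p = 0.199). The oxidative stress median was 0.19 without gctrl-TGA replicate 2, and the unfolded protein response median 0.11 without RESTART v3-TGA replicate 2. The FPKM totals also differed between the arms in TGA, at 466167 and 454971 in gctrl and 488584 and 488959 in RESTART v3.

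**Figure D2:**
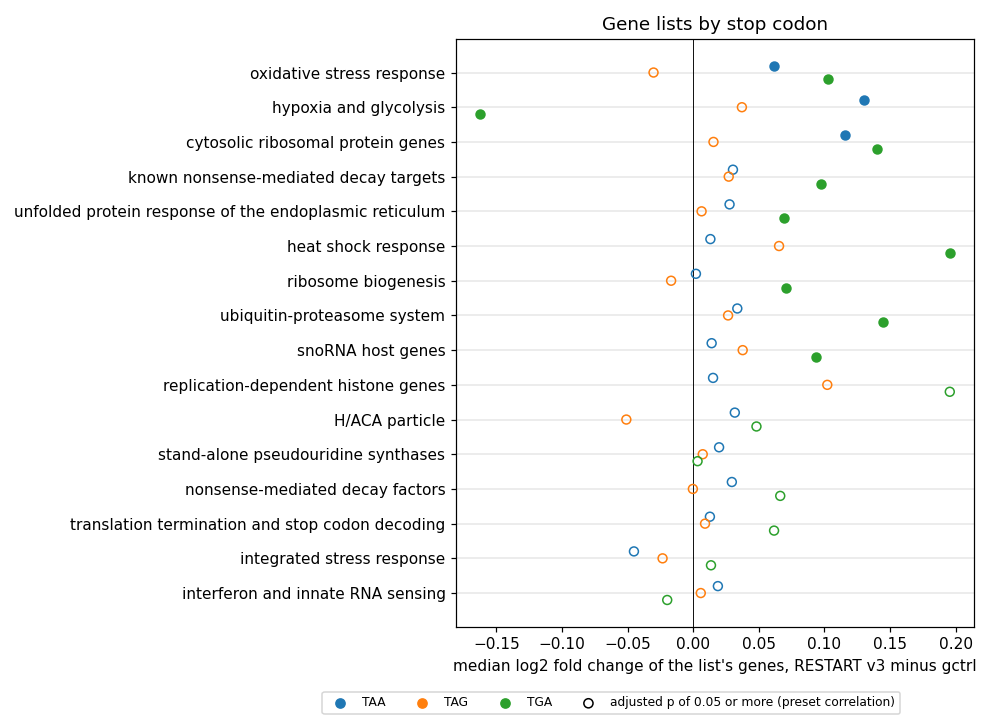
Median log2 fold change of each list's genes (RESTART v3 minus gctrl, horizontal axis) at TAA (blue), TAG (orange) and TGA (green), with filled points for an adjusted p under 0.05 from camera with a preset correlation. The hypoxia and glycolysis list lies at 0.13 in TAA and −0.16 in TGA, signs that held under median-ratio scaling and quantile normalization. No list was called with an estimated correlation, which recovered 0 of 5 moved lists within a codon in simulation.

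Across the 3 stop codons, 3 genes changed in the same direction with RESTART v3. LGALS1, which encodes the lectin galectin-1, rose with a log2 fold change of 0.43 (SE 0.07; 0.28 in TAA, 0.52 in TAG and 0.49 in TGA). The antisense transcript ZNF436-AS1 rose by 0.60 (SE 0.09; 0.84, 0.53 and 0.44). NEAT1, the long noncoding RNA that scaffolds paraspeckles, fell by 0.56 (SE 0.08; −0.45, −0.51 and −0.72). NEAT1 lies on chromosome 11 at 65422798 to 65445540 and LGALS1 on chromosome 22 at 37675636 to 37679802 (GRCh38).

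The adjusted p was 0.0487 for each of the 3, from limma over 11515 genes, of which 1384 had an unadjusted p under 0.05 against 576 expected by chance. Genes next in line, which did not pass, were TYMSOS (0.41), the RNA exosome subunit EXOSC4 (0.34) and BLOC1S4 (0.19) on the higher side. On the lower side they were SLC16A4 (−0.37), CASC4 (−0.18), OS9 (−0.23) and the protease CAPN1 (−0.25). The count fell to 0 under median-ratio scaling, quantile normalization, no filter, no trend or the length and GC correction, and to 0 without TAA or without TGA, while 14 genes were called without TAG and 28 (26 higher, 2 lower) as the average of 3 contrasts. Of the 12 libraries, leaving out gctrl-TAA replicate 2, RESTART v3-TAA replicate 1, gctrl-TAG replicate 1, either RESTART v3-TAG library, gctrl-TGA replicate 2 or RESTART v3-TGA replicate 1 gave 0 genes; without gctrl-TGA replicate 1 or RESTART v3-TGA replicate 2 it was 1, and without gctrl-TAG replicate 2 it was 10.

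In the fit across codons, where a list need not move the same way at each codon, 8 of 28 lists rose as sets. They were ribosomal protein genes (median 0.09, 75 of 78 positive, adjusted p = 3.35e-18), the proteasome list (0.07, adjusted p = 2.69e-06), decay targets (0.06, adjusted p = 0.000475), heat shock (0.07, adjusted p = 0.00405), snoRNA hosts (0.06, adjusted p = 0.00405), the unfolded protein response (0.04, adjusted p = 0.00892), histone genes (0.06, adjusted p = 0.0272) and oxidative stress (0.05, adjusted p = 0.0457). None was called with an estimated correlation (adjusted p = 0.285 for decay targets, the lowest, to 0.399 for oxidative stress). In simulation, with independent genes, that test had recovered 5 of 5 lists across codons. Those lists were moved further than any of the medians given here, so its power at these medians is not known. Of 100 splits of the libraries within stop codons, described below, 8 gave at least 8 lists. For the 8 lists called by arm, fry gave unadjusted p-values from 0.00165 (decay targets) to 0.061 (oxidative stress), with 0.00465 for ribosomal protein genes. Oxidative stress had a median of −0.03 in TAG with 6 of 18 positive, and ribosomal protein genes 0.02 there with 43 of 78 positive. Heat shock had 0.01 in TAA with 11 of 19 positive. Under quantile normalization 0 lists were called, with medians of 0.01 for ribosomal proteins, 0.02 for the proteasome, 0.02 for decay targets, 0.04 for heat shock, 0.01 for snoRNA hosts, 0.01 for the unfolded protein response, 0.09 for histone genes and 0.02 for oxidative stress. The length and GC correction ended the calls of oxidative stress (0.02) and snoRNA hosts (0.04, adjusted p = 0.176 for each), and left ribosomal proteins at 0.04, the proteasome at 0.04 and decay targets at 0.03. The histone list was not tested under it.

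Single libraries decided some of these calls across codons. Oxidative stress was not called without either gctrl-TAA library, either RESTART v3-TAA library, gctrl-TAG replicate 1, gctrl-TGA replicate 1 or either RESTART v3-TGA library (adjusted p up to 0.195), and its median was 0.03 without gctrl-TGA replicate 2. Histone genes were not called without gctrl-TAA replicate 2, RESTART v3-TAA replicate 1, either replicate 1 of TAG or either replicate 1 of TGA (adjusted p up to 0.171). Their median was 0.02 and 0.12 without gctrl-TGA replicate 1 and 2, 0.03 and 0.11 without RESTART v3-TGA replicate 1 and 2, and 0.11 without replicate 2 of either arm in TAG. Heat shock was at 0.04 without RESTART v3-TGA replicate 1 and the unfolded protein response at 0.02 without gctrl-TGA replicate 2, both still called.

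Adjusted over the list alone, 7 proteasome, 4 oxidative stress, 3 decay target, 3 unfolded protein response, 3 histone, 1 ribosomal protein and 1 host gene were higher across codons, 0 heat shock genes were, and 0 members passed over all genes tested.

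The enzymes that RESTART draws on, and the factors that act at stop codons, did not pass in any comparison over all genes tested. Adjusted over the list alone, DKC1 of the H/ACA particle was lower across codons, and of the stand-alone pseudouridine synthases PUS7 was lower in TAA (−0.23) and PUSL1 higher across codons (0.14). DKC1, the dyskerin gene, had log2 fold changes of −0.05, −0.15 and −0.15 in TAA, TAG and TGA and −0.12 across codons (SE 0.03, adjusted p = 0.226). Its H/ACA partners were at 0.07, 0.01 and 0.21 for NOP10, at 0.13, −0.09 and 0.08 for NHP2 and at −0.02, −0.24 and −0.02 for GAR1. The decay factors UPF1 (0.05, −0.07 and 0.02) and SMG1 (−0.01, −0.06 and 0.08) and the release factor genes ETF1 (0.01, 0.06 and 0.09) and GSPT1 (0.00, 0.00 and 0.07) were likewise not called. In TGA, the values of NHP2, ETF1 and GSPT1 turned slightly negative under quantile normalization.

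The corresponding lists were not called by camera either, with medians given here for TAA, TAG and TGA in that order. They were 0.03, −0.05 and 0.05 for the H/ACA particle, 0.02, 0.01 and 0.00 for the stand-alone pseudouridine synthases, and 0.08, −0.02 and 0.05 for the C/D particle. Termination and stop codon decoding had 0.01, 0.01 and 0.06, and decay factors 0.03, 0.00 and 0.07. Lists of tRNA biology had 0.00, −0.03 and 0.06 (processing, export and decay), −0.02, 0.01 and 0.01 (RNA polymerase III) and 0.02, −0.02 and 0.02 (aminoacyl-tRNA synthetases). Translation factors had 0.03, 0.01 and 0.05 and ribosome-associated quality control 0.04, 0.00 and 0.01.

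Immune, stress and growth lists other than those above were not called by camera in any codon. Interferon and innate RNA sensing genes had medians of 0.02, 0.01 and −0.02, and the integrated stress response list −0.05, −0.02 and 0.01. Nuclear factor kappa B targets had 0.05, −0.08 and 0.07, p53 targets −0.02, 0.04 and −0.07, and immediate early genes −0.01, −0.05 and 0.03. Cell cycle lists had −0.03, 0.03 and 0.03 (G2/M) and 0.04, 0.00 and 0.01 (G1/S), and cholesterol synthesis 0.05, −0.02 and 0.00. Median, mean and test direction differed in sign for 4, 6 and 2 lists in TAA, TAG and TGA and 5 across codons, none of them called, among them interferon in TAA and ribosome biogenesis in TAA (median 0.00, test downward). Markers of fibroblasts and of squamous and cervical lines had 1 tested member each (COL1A1 and CDKN2A) and were not tested as lists. The mitochondrial and spliceosomal RNA lists had 0 tested members, and the RNA polymerase III transcripts 1 (RPPH1).

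Whether a gene's response differed between stop codons was tested directly. The interaction called 0 of 11515 genes with limma's F test, with a lowest adjusted p of 0.107 and 1619 genes at an unadjusted p under 0.05 against 576 expected by chance. The pairwise differences called 0 genes each, with lowest adjusted p-values of 0.0876 (TAG and TAA), 0.275 (TGA and TAA) and 0.0515 (TGA and TAG) and 1479, 1052 and 1494 genes at an unadjusted p under 0.05. Across genes, fold changes had a Pearson r of −0.10 between TAA and TAG, 0.20 between TAA and TGA and 0.07 between TAG and TGA. The differences between replicates, handled the same way, gave −0.02, 0.00 and 0.18. HMOX1, at 0.88 in TGA and 0.45 in TAA, is thus not shown to differ between codons.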

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

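For SNORA19, the tests on other snoRNAs and on a transfected guide were chosen only after the result was seen; the test on genes of matched expression was written after quantile normalization of the lists had been seen but before its own values were. For 13 of 84 tests, a gene list responded differently at one stop codon than at another, by camera's test of the difference with a preset correlation. With an estimated correlation 0 of 84 passed (lowest adjusted p = 0.377).

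From TAA to TAG, the median difference in log2 fold change was −0.10 for ribosomal protein genes (−0.0973) and −0.10 for oxidative stress genes (−0.0994). From TAA to TGA it was −0.28 for hypoxia and glycolysis, 0.12 for the proteasome list, 0.17 for heat shock and 0.09 for ribosome biogenesis (0.0865). From TAG to TGA it was 0.13 for ribosomal protein genes, 0.14 for the proteasome list, −0.17 for hypoxia and glycolysis, 0.14 for oxidative stress, 0.11 for tRNA processing, 0.10 for ribosome biogenesis and −0.13 for p53 targets.

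Several of these calls depended on the normalization or on 1 library. Quantile normalization ended 7: ribosomal protein genes from TAA to TAG and from TAG to TGA (adjusted p = 0.334 and 0.478, medians −0.02 and 0.03), oxidative stress in the same 2 differences (0.134 for each), ribosome biogenesis from TAA and from TAG to TGA (0.236 and 0.285) and the proteasome from TAG to TGA (0.072). From TAA to TAG, oxidative stress was not called without either replicate 2 of TAA (adjusted p = 0.1 and 0.109 for gctrl and RESTART v3), gctrl-TAG replicate 2 (0.152) or either RESTART v3-TAG library (0.0506 and 0.0567), and ribosomal protein genes were at −0.06 without gctrl-TAA replicate 2. From TAA to TGA, ribosome biogenesis was not called without RESTART v3-TAA replicate 1 (0.0582) or RESTART v3-TGA replicate 1 (0.288), and was at 0.05 without gctrl-TAA replicate 1 or gctrl-TGA replicate 2. The proteasome was at 0.18 there without gctrl-TGA replicate 1 and heat shock at 0.11 without gctrl-TGA replicate 2.

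From TAG to TGA, p53 targets were not called without gctrl-TAG replicate 1 (adjusted p = 0.105), RESTART v3-TAG replicate 2 (0.0908), gctrl-TGA replicate 1 (0.0546) or RESTART v3-TGA replicate 1 (0.419, −0.07). Hypoxia and glycolysis was not called without gctrl-TAG replicate 2 (0.0609, −0.07) and was at −0.30 without gctrl-TAG replicate 1. Oxidative stress was not called without gctrl-TGA replicate 1 (0.0546), nor ribosome biogenesis without RESTART v3-TGA replicate 1 (0.182).

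Hypoxia and glycolysis genes moved in opposite directions in TAA (median 0.13) and TGA (−0.16). Correlation among the genes cannot be told apart from a real difference: with an estimated correlation the unadjusted p was 0.0395, under the bound set in advance. That test decides nothing, because the list was chosen as the one with the smallest p of 84 tests, and after adjustment over them the value was 0.414. The spread between replicates stays open too. Within TAA and TGA, the largest gap between 2 libraries of a group in the list's mean level (0.08, in RESTART v3-TAA) was 0.266 of the difference between codons, between the bounds set in advance, and the 2 gctrl-TAG libraries, outside this difference, lay 0.23 apart, 0.779 of it. A response specific to the construct of each codon is a further candidate explanation that was not tested. The labels give no culture or harvest record that could separate growth conditions from the construct.

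Ribosomal protein genes were higher in TAA and TGA by the test with a preset correlation, and not called with an estimated one (adjusted p = 0.893 and 0.493). With an estimated correlation, 0 of 5 moved lists were recovered within a codon in simulation, so that loss decides nothing. In TAA a correction for transcript length and GC content left a median of 0.07 (0.0736, SD over genes 0.0690), 63.9% of the uncorrected value and still past the threshold with the preset correlation, which argues against that trend as the whole reason, while the gap between replicates reached 0.806 of the difference between the arms, so that this spread could account for it. In TGA the gap was 0.180 of the difference, under the bound set in advance. The 2 gctrl-TAA libraries, outside this comparison, lay 0.088 apart in the list's mean level, against an arm difference of 0.13 in TGA. The spread between replicates thus stays open there too. In TGA the length and GC correction left 0.04 (0.0399, 28.5% of the uncorrected value, adjusted p = 0.0692). There, that trend cannot be told apart from a response because the remainder lies between the bounds set in advance. Other highly expressed genes matched on mean expression also had positive medians, of 0.0645 in TAA (95% bootstrap interval 0.0424 to 0.0826) and 0.0828 in TGA (0.0663 to 0.129), so a trend with expression level may account for much of both; the matched genes averaged 8.21 and 8.12 log2 units against 9.94 and 9.75, since few genes are as high. A change in ribosomal protein mRNA caused by RESTART v3 itself was not separated from these.

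SNORA19 was higher in RESTART v3-TGA by a log2 fold change of 4.15. More transcription of its host gene is argued against by EIF3A, at −0.06 (−0.0602, SE 0.09, adjusted p = 0.812), and a higher yield of the whole RNA class by the other 20 H/ACA snoRNAs, whose median was 0.23 (95% bootstrap interval −0.01 to 0.72, 14 of 20 positive). Reads from a transfected guide built on the SNORA19 scaffold remain a candidate explanation that cannot be told apart from a cellular response, because the gene could be analysed in 1 of 3 tables and the plasmid sequences were not used here. At approximately 5.16 to 22.9 fragments in gctrl, the size of the change is loosely set.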

How the results depend on the processing

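The length and GC correction, quantile normalization of the lists and the other reading of the column names were chosen after seeing the data. The 13 called genes kept their sign under every alternative that could test them (the other column reading aside): HMOX1 was called under 10 of 13, CDC23 and TAF9B under 6 of 13, SNORA19 under 6 of 12 and NEAT1 under 6 of 24. Named genes, whether or not they had passed, gave 2194 values under another pseudocount, filter or scaling, without the trend or with a library left out. Of these, 2047 kept their side of the threshold (35 of them, past it in neither case, changed sign from a value within 1 SE of 0), 94 were no longer past it, 50 newly passed and 3 reversed, all in TGA under quantile normalization: NHP2 (−0.0324), ETF1 (−0.000388) and GSPT1 (−0.000317). A gene that passed in neither case counts as kept. The replicate block, the fit of all 6 groups, the length and GC correction and the left-out codons did not enter these counts.

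Counts of changed genes moved as follows, and the cause was not tested except where fewer libraries or genes entered by construction. At least 5 FPKM gave 3 genes in TAA (0 in the main result) and 11 in TAG (6). In TAG the count was 0 with a 2-fold minimum, without a filter, under quantile normalization, without the trend, in the fit of all 6 groups and after the length and GC correction, and 2 under median-ratio scaling. In TGA (4) it was 1 with a pseudocount of 0.1 FPKM, under median-ratio scaling or without the trend, 0 without a filter or under quantile normalization, 124 in the fit of all 6 groups and 6 (3 higher, 3 lower) after the length and GC correction. Across codons (3) it was 0 without a filter, under median-ratio scaling, quantile normalization, no trend, the length and GC correction, without TAA or without TGA, 14 without TAG and 28 as the average of 3 contrasts. With the last number of the column names read as the arm, 0 genes were called in TAA, TAG, TGA and across codons, and 4, 2, 3 and 1 lists in TAA, TAG, TGA and across codons. In TAA that reading turned the ribosomal protein genes to the lower side (median −0.05, adjusted p = 0.00622). Leaving out 1 library, where the lone library is assumed to vary like the other groups, gave 2 to 38 genes in TAA, 0 to 10 in TAG, 17 to 77 in TGA, 0 to 10 across codons and 0 to 5 for the interaction (0).

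Within a table, replicate numbers showed little pairing of the libraries: deviations of same-numbered libraries correlated at 0.0095, 0.053 and 0.031 in TAA, TAG and TGA. Between tables, the differences between replicates correlated at 0.18 for TAG and TGA, −0.02 for TAA and TAG and 0.00 for TAA and TGA. A structure tied to replicate number and shared by TAG and TGA is thus not excluded. With the replicate block, 4 genes were called in TAA (2 higher, 2 lower), 5 in TAG, 3 in TGA, 2 across codons and 0 for the interaction, and 1 list in TAG. Of these genes, 0, 4, 2 and 2 were among the main calls of TAA, TAG, TGA and across codons. COG6 and SET in TAG, RBM14-RBM4 and SPDYA in TGA and NEAT1 across codons were not called with the block.

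The ratio of the spread between arms to that between replicate numbers was 1.23 in TAA with at least 5 FPKM, 1.09 and 1.17 in TAG with the smaller pseudocount and at least 5 FPKM, and 1.28, 1.39 and 1.26 in TGA with those and under quantile normalization. The correlation of fold changes between TAA and TGA was 0.254 with at least 5 FPKM, and between TAA and TAG −0.196. An estimated correlation, which recovered 0 of 5 moved lists within a codon in simulation, called 0 lists in TAA (3), TGA (9), across codons (8) and between codons (13). Quantile normalization called 1, 2, 0 and 6, and the length and GC correction 2 in TAA, 8 in TGA (5 higher, 3 lower) and 5 across codons. Leaving out 1 library called 2 to 4 lists in TAA, 0 to 2 in TAG, 8 to 14 in TGA, 6 to 9 across codons and 11 to 17 between codons. Quantile normalization sets the highest ranks equal, which is where the ribosomal protein genes lie. At these depths, changes well under 1.5-fold were mostly missed within a codon in simulation.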

Other observations

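No test in this part was chosen after its result was seen. Among small RNAs, the H/ACA snoRNAs had median log2 fold changes of 0.06 in TAA, −0.31 in TAG and 0.24 in TGA, with camera's adjusted p at 0.884, 0.148 and 0.0596. Single members spread widely: SNORA21 was at −1.08 and SNORA77B at 0.88 in TAA, SNORA74D at −0.62 in TAG, and SNORA66 at 0.89 and SNORA26 at 2.01 in TGA, none of which passed over all genes tested. Adjusted over the list alone, 1 H/ACA snoRNA was higher and 2 were lower in TAA, and 6 were higher and 1 was lower in TGA. The C/D snoRNAs had medians of 0.04 in TAA and −0.37 in TGA (adjusted p = 0.179), and the Cajal body RNAs −0.30 in TAG and −0.13 in TGA (adjusted p = 0.42 and 0.11). Few of these RNAs could be compared across codons, since 3 H/ACA snoRNAs were tested in all 3.

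Histone genes had medians of 0.02 in TAA, 0.10 in TAG and 0.20 in TGA, and the H2B genes with the smallest p-values were on the higher side. H2BC12 was at 0.44 in TAA and 0.48 in TGA (adjusted p = 0.0755 and 0.0689), and H2BC15 at 0.66 in TGA (adjusted p = 0.143). H2AC21 went the other way, at −0.86 in TAA and −0.88 in TGA. In TAG the linker histone gene H1-2 was at 0.31 (adjusted p = 0.195). Histone genes have near-identical copies, so single values are uncertain, and H2BC12 across codons was at 0.32 (adjusted p = 0.128). Of the decay targets, GADD45A was at 0.41 in TAG (adjusted p = 0.173) and 0.36 in TGA (adjusted p = 0.269).

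Other splits of the 12 libraries within stop codons were drawn to see how often they give as much as the arms do. Of 100 splits, the real one included, 1 gave as many as 3 genes, the real one, and the highest of the others gave 1. For the count of genes across codons, this argues against a chance split under the main setting only. Splits were not drawn under the alternatives, several of which called 0 genes across codons, so chance is not excluded there. For gene lists, 8 of 100 splits gave at least the real 8, and the highest of the others gave 10, so chance is not excluded for the count of lists across codons.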
